A study of Mus musculus with 56 samples.

How the data were processed

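Of the 56 samples of the series, the 12 nanoCAGE libraries of wild-type gonocytes were analysed, 3 at each of E13.5, E17.5, E19.5 and P2. The other 44 samples (chromatin accessibility, histone modification, chromosome conformation and mutant libraries) were not analysed here. Per the labels, each library was made from 70 ng of total RNA of sorted gonocytes with template-switching oligonucleotides and random primers, amplified by PCR, and given unique molecular identifiers. The deposited files hold raw CAGE tag counts per transcription start site cluster, with no normalisation by the authors, on genome build mm10. The aligner, the clustering tool, the filters on clusters and whether reads sharing an identifier were collapsed are not given in the sources used here, so counting intervals cover counting error only. Each file also holds a library total, which was used as the library size and kept out of the tests. Between 64.3% and 83.0% of each library's tags lay in the 40107 deposited clusters, which had a median width of 103 bp (at most 201), and 6 of which had no tag.

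The design, written before the data were examined, assumed counts per gene. Because the files hold clusters, clusters were summed to genes with the coordinates of 49231 genes of the GRCm38.p6 annotation, which is the mm10 assembly. The table used gives no strand, so a gene's strand was read from the tags: the strand with at least 80% of at least 5 tags within 500 bp of the gene end at which transcription on that strand would start, and otherwise the strand with 80% of the tags of at least 2 clusters in the gene body. The first reading was overruled where its tags were fewer than 50% of the tags on the other strand of the body. This set the strand of 11140 genes from their ends and of 944 from their bodies and left 3131 unresolved. In all, 29719 clusters with 90.5% of tags in clusters went to 11692 genes: 14739 clusters near a 5′ end (72.5% of tags) and 14980 in a gene body (18.0%). A further 7975 clusters (7.23%) were antisense or unresolved and 2413 (2.25%) intergenic. A cluster went to the gene with the nearest 5′ end, and where several lay within 100 bp of that distance to a protein-coding gene first. For 84 of the assigned clusters (0.464%) genes of equal rank were that close, so the choice between them is uncertain. Strand reading from tags can misplace genes with an antisense or divergent neighbour, and tags of paralogs and pseudogenes cannot be told apart from cluster positions. A gene's sum joins its alternative start sites. A cluster far from the annotated 5′ end may be another transcript or no capped start, and is named in the text where it holds most of a named gene's tags.

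Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total 15) left 6144 genes, TMM factors scaled the library totals, and 1 robust quasi-likelihood fit of all 12 libraries with stage as the only term gave the 4 comparisons and the test across 4 stages. P-values were adjusted by Benjamini-Hochberg, with 0.05 as threshold and no threshold on the fold. The biological coefficient of variation was 27.03% for genes and 31.2% for clusters. Files were read and figures drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9. Where a group of 3 libraries had no tag, the fold is a bound against 3 tags over the group, and where it had 1 to 3 tags a ratio of library-size-scaled tags is given with its 95% exact binomial counting interval.

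The 26 gene lists (719 genes, of which 714 were in the annotation and 540 had a cluster) were written before the data were examined and none was taken from these samples. They cover pluripotency and primordial germ cells, Nodal signalling, the piRNA pathway, DNA methylation, H3K9 methylation, Polycomb, lamina and chromatin architecture, meiosis, spermatogonia, S phase, G2 and mitosis, cell cycle inhibitors, imprinted genes, glycolysis, the respiratory chain, mitochondrially encoded proteins, ribosomal proteins, immediate-early and heat-shock genes, early zygotic activation, and markers of Sertoli, Leydig, peritubular and stromal, endothelial, macrophage, erythroid and oocyte cells. No Sertoli marker is in another list. Cdkn1c is both an inhibitor and an imprinted gene, Nanos2 is in the piRNA and spermatogonial lists, and Tcl1 is in the pluripotency and spermatogonial lists. The 17 lists with at least 5 tested genes were tested with camera (preset correlation 0.01, and again with an estimated one) and fry from limma 3.58.1, adjusted over 68 tests. Of 25 camera calls, 6 held with an estimated correlation: pluripotency at E17.5 and at P2 against E13.5, meiosis and spermatogonial genes at P2 against E13.5, and spermatogonial and S phase genes at P2 against E19.5. Family totals (9 families) were compared by an exact two-sided permutation test between stages and by 100000 permutations of the stage labels over the 4 stages.

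Genes were named by a rule fixed before the data were examined. Per comparison it takes the 6 largest rises and 6 largest falls among genes past the threshold with an average log2 CPM of at least 3, an informative symbol and groups of 3 that do not overlap. It also takes up to 3 members with the smallest adjusted p of each list described, and 12 fixed genes whatever the test says. Piwil2 and Piwil4, for example, are fixed genes. Any other gene is said to have been chosen after its values were seen.

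Gene and cluster counts and named genes were recomputed under alternatives set at the start. These were DESeq2 1.42.0 size factors, total tags alone as scale, the DESeq2 and limma-trend tests, no filter, and a CPM of at least 5 in 3 libraries. The last was planned as a stricter filter but is looser than filterByExpr at these library sizes. Further alternatives were only the 6 libraries compared, a replicate block, leaving out each of the 12 libraries, and leaving out mitochondrially encoded and ribosomal protein genes. Gene lists were rerun only with an estimated correlation, the block, each library left out, total tags alone and the Sertoli settings below. Family totals were rerun only with each library left out and with other denominators. An alternative pseudocount, meant for normalised values, was not run because the files hold counts. Chosen after seeing the data were tests of the clusters themselves, tags in clusters as library size, clusters within 500 bp of the 5′ end only, the summed Sertoli markers as a covariate, and leaving out the 4 libraries with more than 1000 CPM of these markers. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold, 14% to 21% of the former and 65% to 76% of the latter were called, and for clusters 8% to 16% and 57% to 65%. A simulated list of 25 genes raised 2-fold was called and none of 40 unchanged lists was. In 20 sets of data simulated without change at most 3 genes were called between E13.5 and E17.5. In 20 further sets, chosen after seeing the data, each gene kept its fitted step with the smaller p, out of E13.5 to E17.5 and E17.5 to E19.5, and the other step was removed.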

Results

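The 5′ ends of RNA were sequenced by nanoCAGE, a cap analysis of gene expression for small RNA amounts. In it template switching is meant to mark the capped end of each transcript, and whether each tag came from a capped end was not tested. The cells were C57BL/6 mouse gonocytes, the germ cells of the fetal and newborn testis, sorted on an Mvh-Venus reporter. Mvh is the germ cell RNA helicase encoded by Ddx4. Each of the 12 libraries was made from 70 ng of RNA, with 3 replicates at E13.5 (E for embryonic day), E17.5, E19.5 and postnatal day 2 (P2). Total tags per library were 533011, 379933 and 413594 at E13.5 and 577014, 462816 and 1452345 at E17.5. They were 307237, 285335 and 348355 at E19.5 and 358383, 728416 and 337490 at P2. The question was how the use of transcription start sites changes as gonocytes pass from the end of primordial germ cell life to the newborn testis. Levels are given per gene in CPM, tag counts scaled to a common library total with edgeR's TMM factors, as mean ± SD with n = 3 libraries. Changes are log2 ratios of the later to the earlier stage ± SE, with Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood F-test. These p-values measure the spread between these libraries, which may be technical rather than a spread between animals.

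Of 6144 genes tested, 3274 changed across the 4 stages (3669 at an unadjusted p under 0.05). The highest mean level of these 3274 genes fell at E13.5 for 1084, at E17.5 for 1220, at E19.5 for 415 and at P2 for 555. The first step, from E13.5 to E17.5, held 2809 changed genes, the second step 749 and the step from E19.5 to P2 495. Between the ends of the course, E13.5 and P2, 1374 genes differed. In a principal component analysis the first component took 43.1% of the variance and set E13.5 against E17.5, and the second took 15.1% and set P2 apart. Correlations across genes between replicates ranged from 0.876 to 0.908 at E13.5, 0.879 to 0.901 at E17.5, 0.742 to 0.835 at E19.5 and 0.877 to 0.915 at P2. E19.5 replicate 3 lay at 32.6 on the first component, against 9.81 and 10.1 for E19.5 replicates 1 and 2. Summed Sertoli cell markers, genes of the somatic cells that nurse the germ line, were at 2099 and 2292 CPM of total tags in E19.5 replicates 1 and 2 and at 138 in replicate 3. They were also above 1000 in E13.5 replicate 3 (2070) and P2 replicate 3 (1831), and lay between 138 and 887 in the other 8 libraries. The gene count of each comparison is therefore also given without these 4 libraries and with the Sertoli marker sum as a covariate, both chosen after seeing the data. The first leaves E19.5 with 1 library, whose spread is then assumed to equal that of the other stages.

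**Figure D1:**
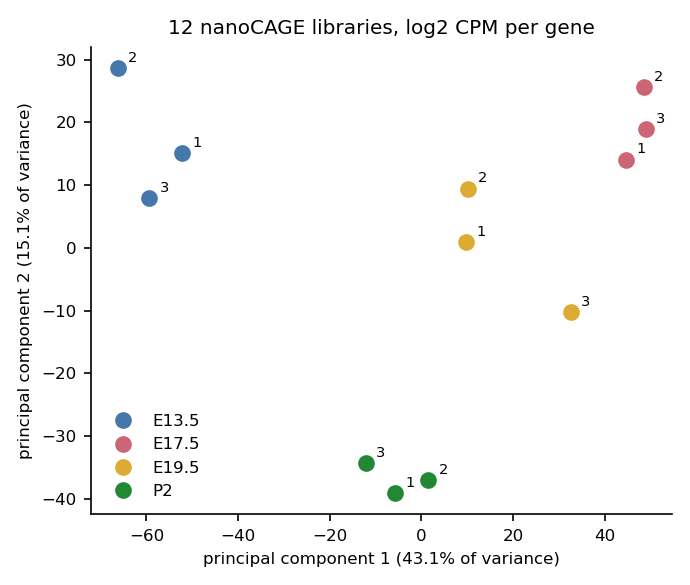
Principal component analysis of the 12 libraries over the 6144 tested genes, first component (43.1% of the variance) on the x axis and second (15.1%) on the y axis, one point per library and one colour per stage. E13.5 libraries lie between -66.3 and -52.2 on the first component and E17.5 libraries between 44.6 and 48.9.

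**Figure D2:**
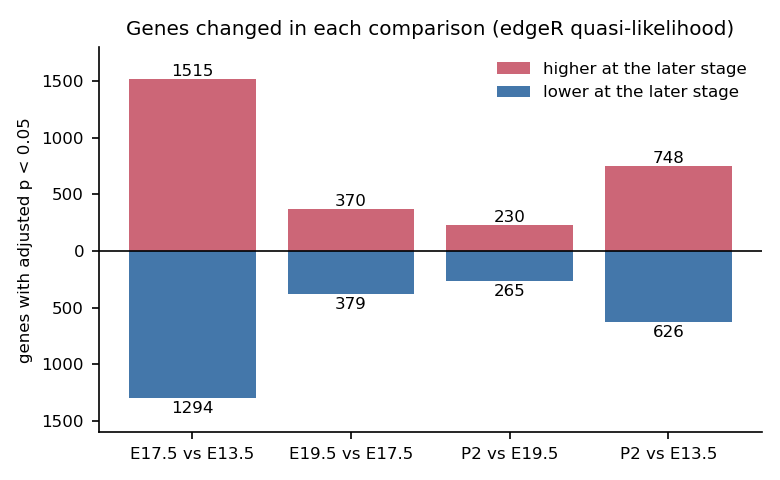
Number of genes that changed in each comparison (edgeR, adjusted p under 0.05), drawn upwards for genes higher and downwards for genes lower at the later stage. The step from E13.5 to E17.5 has 1515 genes higher and 1294 lower.

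Between E13.5 and E17.5 8 of 17 pluripotency genes, 25 of 36 G2 and mitosis genes and 17 of 31 S phase genes fell, and 15 of 23 piRNA pathway genes rose. With an estimated correlation only the pluripotency list of these kept its call. Mael, which acts in piRNA biogenesis and transposon silencing, rose from 51.9 ± 31.3 to 924 ± 103 CPM (log2 ratio 4.10 ± 0.31, adjusted p = 2.4e-11). L1td1, an RNA-binding protein of pluripotent cells, fell from 940.4 ± 112.9 to 101 ± 31.8 CPM (-3.18 ± 0.28, adjusted p = 1.02e-10). Dnmt3l, the cofactor of de novo DNA methylation, had no tag in the E13.5 libraries and 148 ± 37.7 CPM at E17.5, at least 60.5-fold higher (adjusted p = 7.84e-06). Its main cluster (chromosome 10, 78049821 to 78050015) starts 7534 bp from the annotated 5′ end. In all, 1515 genes rose and 1294 fell (2809; 3239 at an unadjusted p under 0.05), with a median absolute log2 ratio of 1.66 among them.

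Among the 6 largest rises under the naming rule, which needs groups of 3 libraries that do not overlap (10% of unchanged genes would also show this), 5 besides Dnmt3l had no tag at E13.5. Ccdc113 (chromosome 8, 95538264 to 95538447), Wdr66 and Cfap45, which encode proteins of motile cilia and flagella, were at least 118-fold, 83.1-fold and 72.0-fold higher at E17.5, at 264 ± 88.3, 177 ± 83.5 and 142 ± 63.6 CPM. The matrix protein gene Thbs4 and the adhesion gene Clstn3 were at least 63.9-fold and 65.8-fold higher. The largest falls included Lefty1 (chromosome 1, 180934993 to 180935070), an antagonist of Nodal signalling, which went from 59.1 ± 11.03 CPM to no tag, at least 43.8-fold lower. Ubqln4, a proteasome shuttle factor, and the lipase gene Lipg also went to no tag, at least 44.9-fold and 16.2-fold lower. Mycn, a proto-oncogene of proliferating progenitors, went from 47 tags to 1, a ratio of 76.2-fold (counting interval 13.0 to 3073), and the metalloproteinase gene Mmp15 from 111 tags to 2, a ratio of 90.0-fold (counting interval 24.3 to 752). The adjusted p-values of these genes ranged from 3.98e-12 to 4.08e-05.

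Of 23 measured piRNA pathway genes 15 rose, none fell and 8 did not pass (15 and 0 adjusted over the list alone; median log2 ratio 1.86). As a list they ranked above the other genes (camera adjusted p = 2.39e-12), and adjusted p = 0.0964 with an estimated correlation (range over its alternatives 6.96e-15 to 0.0964). Tex15 rose from 86.8 ± 34.1 to 716 ± 87.7 CPM (3.02 ± 0.26, adjusted p = 6.65e-11), Piwil2 from 45.9 ± 14.3 to 355 ± 87.3 and Piwil4 from 8.11 ± 14.1 to 201 ± 38.7. Piwil2 and Piwil4 encode MILI and MIWI2, the PIWI proteins of fetal germ cells. Spocd1, which links piRNAs to DNA methylation, went from 3 tags to 550, a ratio of 113.1-fold (counting interval 38.5 to 550.0). Of 17 pluripotency and primordial germ cell genes 8 fell and none rose (8 and 0 adjusted over the list alone; median -1.30; camera adjusted p = 6.1e-05), and adjusted p = 0.0328 with an estimated correlation (range over its alternatives 6.43e-06 to 0.0328). Dppa5a, an RNA-binding pluripotency factor, fell from 295 ± 47.2 to 11.8 ± 6.09 CPM (-4.55 ± 0.40, adjusted p = 8.15e-11) and Tcea3, an elongation factor, from 263 ± 96.7 to 51.5 ± 12.1. Summed over each list, piRNA pathway genes took 3278 ± 496 CPM at E13.5 and 9092 ± 177 at E17.5, and pluripotency genes 2687 ± 235 and 864 ± 36.9. Pou5f1, which encodes the pluripotency factor OCT4, was at 218 ± 56.3 and 154 ± 14.8 CPM and did not pass (adjusted p = 0.166).

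Many genes of the cell cycle fell as well. Of 36 G2 and mitosis genes 25 fell and none rose (26 and 0 adjusted over the list alone; median -1.74; camera adjusted p = 3.01e-09), and adjusted p = 0.149 with an estimated correlation (range over its alternatives 3.43e-11 to 0.149). Birc5, the survivin subunit of the chromosomal passenger complex, fell from 275 ± 43.2 to 20.5 ± 6.15 CPM (-3.69 ± 0.36, adjusted p = 7.88e-10), and Top2a, the mitotic topoisomerase, from 554 ± 143 to 102 ± 7.72. Of 31 S phase genes 17 fell and 1 rose (18 and 1 adjusted over the list alone; median -1.05; camera adjusted p = 6e-05), and adjusted p = 0.0569 with an estimated correlation (range over its alternatives 1.27e-05 to 0.0569). Mcm2, part of the replicative helicase, fell from 747 ± 282 to 122 ± 27.4 CPM (-2.60 ± 0.28, adjusted p = 5.33e-09). Mki67, the Ki-67 proliferation marker, fell from 154 ± 77.5 to 11.8 ± 6.73 CPM (-3.49 ± 0.57, adjusted p = 4.68e-05). Of 11 cell cycle inhibitors 1 rose and 4 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.408). Cdkn2a, the Ink4a/Arf locus, rose from 16.9 ± 11.9 to 98.8 ± 25.2 CPM and Foxo3 fell from 65.4 ± 12.9 to 20.7 ± 9.46.

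Chromatin genes moved in both directions. Of 23 nuclear lamina and chromatin architecture genes 11 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.79; camera adjusted p = 0.0332), and adjusted p = 0.464 with an estimated correlation (range over its alternatives 0.00298 to 0.464). The list's call was lost without E17.5 replicate 3 (adjusted p = 0.0509) and with the Sertoli covariate (0.0614). Lmnb1, the B-type lamin, fell from 359 ± 106 to 36.4 ± 6.95 CPM (-3.31 ± 0.39, adjusted p = 3.05e-07). Ctcfl, a germ cell paralog of CTCF, went from 1 tag to 87, a ratio of 53.7-fold (counting interval 9.38 to 2144). Of 10 DNA methylation genes 3 rose and 4 fell (3 and 5 adjusted over the list alone). Tet1, the 5-methylcytosine oxidase, fell from 166 ± 11.8 to 7.01 ± 6.59 CPM (-4.55 ± 0.56, adjusted p = 1.22e-07), and Hells, a chromatin remodeller needed for DNA methylation, from 2918 ± 549 to 511 ± 57.4. Dnmt3a, a de novo methyltransferase, rose from 57.1 ± 8.37 to 204 ± 42.3 CPM (1.83 ± 0.31), with its main cluster 69777 bp from the annotated 5′ end. Of 23 H3K9 methylation and heterochromatin genes 3 rose and 9 fell (4 and 10 adjusted over the list alone), among them Cbx1, which fell from 604 ± 182 to 54.5 ± 25.4, and the H3K9 methyltransferase gene Ehmt2, which rose from 182 ± 71.3 to 661 ± 81.4. Of 16 Polycomb group genes 5 rose and 4 fell (the same numbers adjusted over the list alone), with Ezh1 up from 31.6 ± 18.1 to 246 ± 15.1. Camera gave adjusted p = 0.309 for DNA methylation, 0.0882 for H3K9 methylation and 0.833 for Polycomb.

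Of 18 meiosis genes 8 rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.182). Mei1 had no tag at E13.5 and 26.1 ± 6.25 CPM at E17.5, at least 11.7-fold higher, and Tex12, of the synaptonemal complex, rose from 10.4 ± 4.67 to 72.7 ± 43.7. Of 24 spermatogonial genes 7 rose and 8 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.937). Etv5, a transcription factor of spermatogonial stem cells, fell from 78.9 ± 12.7 to 1.06 ± 1.83 CPM (-5.32 ± 0.65, adjusted p = 6.39e-08), while the germ cell surface gene Tex101 went from 1 tag to 385, a ratio of 237-fold (counting interval 42.4 to 9404). Of 11 imprinted genes 4 rose and 3 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.833). Peg3, paternally expressed, fell from 451 ± 80.7 to 27.3 ± 9.20 CPM (-4.13 ± 0.32, adjusted p = 7.32e-12). Of 13 glycolysis genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; 0.474), with the lactate dehydrogenase genes apart. Ldha rose from 9.20 ± 5.90 to 78.6 ± 23.2 CPM and Ldhb fell from 125 ± 16.1 to 13.4 ± 5.47. Of 46 respiratory chain genes 11 rose and 8 fell (the same numbers adjusted over the list alone; 0.989), and of 56 cytosolic ribosomal protein genes 10 rose and 6 fell (9 and 6 adjusted over the list alone; 0.833).

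Several markers of stress and of Sertoli cells were lower at E17.5. Of 11 immediate-early and heat-shock genes 8 fell and none rose (8 and 0 adjusted over the list alone; median -2.27; camera adjusted p = 0.00677), and adjusted p = 0.519 with an estimated correlation (range over its alternatives 0.00015 to 0.519). Egr1, an immediate-early transcription factor, fell from 93.5 ± 50.4 to 21.8 ± 7.58 CPM (-2.03 ± 0.40, adjusted p = 8.65e-05). Of 15 Sertoli cell markers 6 fell and none rose (6 and 0 adjusted over the list alone; median -1.70; camera adjusted p = 0.0383), and adjusted p = 0.713 with an estimated correlation (range over its alternatives 6.65e-05 to 0.866). That call was lost without E13.5 replicate 3 (0.0777) and without E17.5 replicate 2 (0.0717). Sox9, the Sertoli cell transcription factor, fell from 54.1 ± 40.5 to 4.11 ± 6.44 CPM (-3.87 ± 1.10, adjusted p = 0.011), a call lost without E17.5 replicate 3 (0.0708; range over its alternatives 8.95e-07 to 0.198). List median, mean and test differed in sign for DNA methylation (-0.73, 0.14 and down), spermatogonial genes (-0.10, -0.18 with members at 0 set to their bound, 0.28 and down), imprinted genes (-0.15, 0.065 and down) and ribosomal proteins (0.20, -0.029 and down). Without the 4 Sertoli-high libraries 3096 genes changed, 2395 of them among the 2809, and with the covariate 1885, of which 1770 were shared. Removing these libraries does not level the Sertoli markers in this step. E13.5 replicates 1 and 2 stayed at 880 and 887 CPM of total tags, against 162 to 275 at E17.5. Scaling by total tags alone moved the median log2 ratio of all genes to -0.16, and 1178 genes were then higher and 1578 lower.

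Between E17.5 and E19.5 10 of 23 piRNA pathway genes fell and 13 did not pass, and the list lost its call with an estimated correlation. Mov10l1, the helicase that starts piRNA processing, fell from 981 ± 242 to 352 ± 22.8 CPM (-1.48 ± 0.24, adjusted p = 0.000139), and Piwil4 (chromosome 9, 14740606 to 14740745) from 201 ± 38.7 to 25.6 ± 0.66 (-2.96 ± 0.51, adjusted p = 0.00067). Ccnd2, a G1 cyclin, rose from 6.55 ± 6.18 to 87.2 ± 41.0 CPM (4.14 ± 0.56, adjusted p = 2.2e-05), and Dmrt1, a regulator of male germ cell fate that Sertoli cells also express, from 31.7 ± 16.0 to 152 ± 24.8 (2.33 ± 0.36, adjusted p = 6.87e-05). In all, 370 genes rose and 379 fell (749; 1719 at an unadjusted p under 0.05), with a median absolute log2 ratio of 1.39. Beside both directions, summed Sertoli markers went from 262 ± 61.1 CPM at E17.5 to 1618 ± 1283 at E19.5.

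Of 23 piRNA pathway genes 10 fell, none rose and 13 did not pass (12 and 0 adjusted over the list alone; median -0.88; camera adjusted p = 9.95e-09), and adjusted p = 0.197 with an estimated correlation (range over its alternatives 1.72e-09 to 0.197). Stag3, a meiotic cohesin subunit with its main cluster 7966 bp from the annotated 5′ end, fell from 402 ± 31.5 to 169 ± 4.78 CPM (-1.25 ± 0.26, adjusted p = 0.00177) and was the 1 of 18 meiosis genes that passed (3 fell adjusted over the list alone; camera adjusted p = 0.907). Tnnc2, a troponin gene, fell from 229.8 ± 56.0 to 29.9 ± 3.42 CPM (-2.92 ± 0.40, adjusted p = 2.2e-05). Among cell cycle genes few passed: 4 of 36 G2 and mitosis genes fell and 2 rose (6 and 4 adjusted over the list alone; camera adjusted p = 0.789), and 3 of 31 S phase genes fell and 2 rose (the same numbers adjusted over the list alone; 0.715). Cenpf, a kinetochore protein, fell from 625 ± 88.7 to 219 ± 47.8 CPM (-1.52 ± 0.22, adjusted p = 3.86e-05), and Cdca8, of the chromosomal passenger complex, from 627 ± 66.7 to 333 ± 71.7. The respiratory chain subunit gene Ndufa12 rose from 38.7 ± 6.59 to 122 ± 23.2 CPM (1.64 ± 0.36, adjusted p = 0.00273), in a list in which 2 of 46 rose and 1 fell (the same numbers adjusted over the list alone; 0.931). Median, mean and test differed in sign for H3K9 methylation (-0.005, 0.25 and up), meiosis (0.11, 0.029 and down) and the respiratory chain (-0.055, 0.055 and up).

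Sertoli, stress and inhibitor lists ranked higher over the E19.5 libraries, the first pair from replicates 1 and 2. Sertoli markers summed to 2290 and 2426 CPM there and to 139 in replicate 3, and stress genes to 1335, 1350.2 and 523. Of 15 Sertoli markers 2 rose and 13 did not pass (11 rose adjusted over the list alone; median 3.10; camera adjusted p = 6.1e-05), and adjusted p = 0.519 with an estimated correlation (range over its alternatives 4.58e-13 to 0.799). Without the 4 Sertoli-high libraries, which were chosen by this list's sum, the list's median turned to -0.89. Sox9 was at 4.11 ± 6.44 and 57.3 ± 42.2 CPM. Of 11 immediate-early and heat-shock genes 4 rose and 1 fell (6 and 2 adjusted over the list alone; median 2.16; camera adjusted p = 0.00963), and adjusted p = 0.519 with an estimated correlation (range over its alternatives 2.87e-06 to 0.596). Egr1 rose from 21.8 ± 7.58 to 158 ± 54.8 CPM (2.77 ± 0.40, adjusted p = 3.52e-05). Of 11 cell cycle inhibitors 1 rose (1 adjusted over the list alone; camera adjusted p = 0.0337), and adjusted p = 0.344 with an estimated correlation (range over its alternatives 0.00337 to 0.344). That was Cdkn2d, an Ink4 inhibitor, which went from 3 tags to 18, a ratio of 14.5-fold (counting interval 4.22 to 76.7) with adjusted p = 0.00744, or 0.0589 without E19.5 replicate 2 (range over its alternatives 0.0036 to 0.166). The inhibitor list's call was lost without E17.5 replicate 2 (0.0575) or 3 (0.0618) and without E19.5 replicate 2 (0.0688) or 3 (0.145). Of 56 cytosolic ribosomal protein genes 1 rose and 4 fell (1 and 3 adjusted over the list alone; median -0.41; camera adjusted p = 0.023), and adjusted p = 0.682 with an estimated correlation (range over its alternatives 0.000881 to 0.891). This call was lost without E17.5 replicate 2 (0.432), E19.5 replicate 1 (0.0617) or E19.5 replicate 2 (0.26).

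The 749 changed genes became 343 without E17.5 replicate 3, 320 without E19.5 replicate 1 and 433 without E19.5 replicate 2. With the Sertoli covariate 290 genes changed (124 higher, 166 lower, 267 of them among the 749), and without the 4 Sertoli-high libraries 171 (76 higher, 95 lower, 136 shared). Of the 54 genes taken by the naming rule that passed, 31 also passed with the covariate, 14 without the 4 libraries and 10 under every alternative run. These 10 were Mov10l1, Piwil4, Ccnd2, Dmrt1, Stag3, Tnnc2, Cenpf, Cdca8, Ndufa12 and Egr1. Scaling by total tags alone moved the median of all genes to 0.11 and gave 479 genes higher and 210 lower, and scaling by tags in clusters, chosen after seeing the data, gave 485 and 275.

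Between E19.5 and P2 12 of 31 S phase genes, 15 of 36 G2 and mitosis genes and 9 of 24 spermatogonial genes rose. The G2 and mitosis list lost its call with an estimated correlation. Mcm5 and Mcm2, subunits of the replicative helicase, rose from 33.8 ± 16.9 to 198 ± 59.9 CPM (2.54 ± 0.37, adjusted p = 3.88e-05) and from 106 ± 41.2 to 356 ± 45.2 (1.76 ± 0.29, adjusted p = 0.000273). Uhrf1, which recruits DNMT1 to replicating DNA, rose from 24.3 ± 14.9 to 186 ± 21.6 CPM (2.88 ± 0.40, adjusted p = 2.86e-05). Mcam, a surface protein of spermatogonial cells, rose from 19.0 ± 16.2 to 119 ± 11.9 CPM (2.70 ± 0.46, adjusted p = 0.000291). In all, 230 genes rose and 265 fell (495; 1456 at an unadjusted p under 0.05), with a median absolute log2 ratio of 1.57.

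Of 31 S phase genes 12 rose and none fell (19 and 0 adjusted over the list alone; median 1.23; camera adjusted p = 6.1e-13), and adjusted p = 0.00566 with an estimated correlation (range over its alternatives 9.5e-14 to 0.00566). Of 36 G2 and mitosis genes 15 rose and none fell (22 and 0 adjusted over the list alone; median 0.99; camera adjusted p = 9.83e-14), and adjusted p = 0.0569 with an estimated correlation (range over its alternatives 7.41e-24 to 0.0569). Kif2c, a mitotic kinesin, rose from 6.93 ± 6.31 to 76.0 ± 23.6 CPM (3.48 ± 0.61, adjusted p = 0.000448), and Ccna2, cyclin A2, from 16.9 ± 3.85 to 112 ± 3.29. Mki67 was at 41.0 ± 38.2 and 76.5 ± 23.2 CPM and did not pass (adjusted p = 0.334). Of 24 spermatogonial genes 9 rose and none fell (11 and 0 adjusted over the list alone; median 1.24; camera adjusted p = 5.17e-09), and adjusted p = 0.00566 with an estimated correlation (range over its alternatives 3.78e-09 to 0.00566). Tcl1, a kinase coactivator, rose from 9.71 ± 5.59 to 84.7 ± 32.2 CPM (3.06 ± 0.56, adjusted p = 0.000628). Zbtb16, which encodes the stem cell factor PLZF, rose from 5.31 ± 2.91 to 54.6 ± 5.54 CPM (3.26 ± 0.69, adjusted p = 0.00271), or 0.151 without the 4 Sertoli-high libraries (range over its alternatives 0.000506 to 0.151). Summed over the list, S phase genes took 2232 ± 101 CPM at E19.5 and 4355 ± 139.5 at P2, and G2 and mitosis genes 2625 ± 683 and 4984 ± 322.

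Of 10 DNA methylation genes 4 rose and none fell (5 and 2 adjusted over the list alone; median 1.11; camera adjusted p = 0.00473), and adjusted p = 0.101 with an estimated correlation (range over its alternatives 0.000828 to 0.101). Dnmt1, the maintenance methyltransferase, rose from 335 ± 49.0 to 749.9 ± 65.8 CPM (1.17 ± 0.21, adjusted p = 0.000465), with its main cluster 6933 bp from the annotated 5′ end. Dnmt3l was at 36.8 ± 36.8 and 8.25 ± 9.05 CPM and did not pass (adjusted p = 0.113). Spocd1 fell from 87.7 ± 39.3 to 18.3 ± 10.7 CPM (-2.12 ± 0.43, adjusted p = 0.00197), 1 of 2 piRNA pathway genes of 23 that fell while 1 rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.931). Of 18 meiosis genes 3 rose (3 adjusted over the list alone; median 0.28; camera adjusted p = 0.0347), and adjusted p = 0.197 with an estimated correlation (range over its alternatives 0.0284 to 0.267). Smc1b, a meiotic cohesin subunit, rose from 417 ± 45.1 to 928 ± 88.1 CPM (1.15 ± 0.21, adjusted p = 0.000517). The meiosis call was lost without E13.5 replicate 2 (0.0733), E19.5 replicate 1 (0.131) or 2 (0.227), or P2 replicate 1 (0.16) or 2 (0.0678). Of 11 imprinted genes 3 fell (4 adjusted over the list alone; median -0.95; camera adjusted p = 0.00329), and adjusted p = 0.162 with an estimated correlation (range over its alternatives 0.000258 to 0.162). Grb10, a maternally expressed growth inhibitor, fell from 120.2 ± 58.2 to 18.5 ± 8.48 CPM (-2.68 ± 0.42, adjusted p = 0.00015), a call lost from clusters near the 5′ end alone (0.0976; range over its alternatives 2.19e-07 to 0.0976). Of 56 ribosomal protein genes 4 rose (3 adjusted over the list alone; median 0.22; camera adjusted p = 0.023), and adjusted p = 0.682 with an estimated correlation (range over its alternatives 0.000421 to 0.682). That call was lost without E19.5 replicate 1 (0.0568) or 2 (0.26) and without P2 replicate 1 (0.114).

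Among the genes with the largest moves between E19.5 and P2, of which only some are named here, were Kcnj15 and Ecm1. Kcnj15, a potassium channel gene, went from 1 tag to 136, a ratio of 68.7-fold (counting interval 12.1 to 2734). Its main cluster lay 33994 bp from the annotated 5′ end. Ecm1, a matrix protein gene, went from 2 tags to 119, a ratio of 30.1-fold (counting interval 8.14 to 251). Cenpm, of the kinetochore, went from 3 tags to 119, a ratio of 20.04-fold (counting interval 6.69 to 98.6). Phf10, a chromatin remodeller subunit, fell from 78.7 ± 9.70 to 6.30 ± 3.49 CPM (-3.43 ± 0.50, adjusted p = 3.77e-05). Lmna, the A-type lamin, rose from 20.3 ± 2.60 to 98.0 ± 30.8 CPM (2.29 ± 0.48, adjusted p = 0.00235), with its main cluster 6582 bp from the annotated 5′ end. Summed Sertoli markers were at 1618 ± 1283 CPM at E19.5 and 798 ± 700.3 at P2, and 1 of 15 fell (1 adjusted over the list alone; camera adjusted p = 0.135). Median, mean and test differed in sign for pluripotency genes (-0.42, -0.31 with members at 0 set to their bound, -0.24 and up), Polycomb genes (-0.049, -0.056 and up), lamina genes (-0.035, 0.10 and up) and cell cycle inhibitors (0.13, -0.028 and up). The 495 changed genes became 279 without E19.5 replicate 1, 266 without E19.5 replicate 2, 202 without P2 replicate 1 and 232 without P2 replicate 2. With the Sertoli covariate 644 genes changed and without the 4 Sertoli-high libraries 171 (127 of them among the 495), and 20 of the 51 genes taken by the naming rule passed under every alternative run. Scaling by total tags alone moved the median of all genes to 0.34 and gave 644 genes higher and 116 lower, and scaling by tags in clusters gave 334 and 209.

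From E13.5 to P2, 9 of 17 pluripotency genes fell, and 14 of 23 piRNA pathway, 9 of 18 meiosis and 12 of 24 spermatogonial genes rose. The piRNA list lost its call with an estimated correlation. L1td1 fell from 940.4 ± 112.9 to 15.5 ± 10.3 CPM (-5.95 ± 0.35, adjusted p = 1.55e-14), and Pou5f1 from 218 ± 56.3 to 59.1 ± 26.97 (-1.81 ± 0.31, adjusted p = 5.63e-05). Dppa3, a primordial germ cell factor that protects DNA methylation in the zygote, went from 47.9 ± 5.70 CPM to no tag, at least 28.8-fold lower. Gfra1, the GDNF coreceptor of spermatogonial stem cells, had no tag at E13.5 and 47.3 ± 5.21 CPM at P2, at least 21.5-fold higher (chromosome 19, 58454356 to 58454547). In all, 748 genes were higher and 626 lower at P2 (1374; 2110 at an unadjusted p under 0.05), with a median absolute log2 ratio of 1.59.

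Of 17 pluripotency genes 9 fell and none rose (10 and 1 adjusted over the list alone; median -1.81; camera adjusted p = 5.17e-09), and adjusted p = 0.00566 with an estimated correlation (range over its alternatives 3.17e-10 to 0.00566). Of 24 spermatogonial genes 12 rose and none fell (14 and 0 adjusted over the list alone; median 1.18; camera adjusted p = 2.77e-07), and adjusted p = 0.0248 with an estimated correlation (range over its alternatives 1.25e-07 to 0.0248). Ccnd2 rose from 5.96 ± 1.66 to 146 ± 9.28 CPM (4.55 ± 0.54, adjusted p = 1.42e-07), and Zbtb16 went from 1 tag to 100, a ratio of 75.1-fold (counting interval 13.2 to 2997). Of 23 piRNA pathway genes 14 rose and none fell (15 and 0 adjusted over the list alone; median 1.39; camera adjusted p = 3.01e-09), and adjusted p = 0.162 with an estimated correlation (range over its alternatives 3.4e-13 to 0.162). Mael was at 325 ± 67.8 CPM at P2 (2.60 ± 0.31, adjusted p = 2.96e-07) and Tex15 at 375 ± 13.54 (2.09 ± 0.26). Of 18 meiosis genes 9 rose and none fell (11 and 0 adjusted over the list alone; median 1.18; camera adjusted p = 0.000303), and adjusted p = 0.0402 with an estimated correlation (range over its alternatives 6.19e-05 to 0.0402). Meioc, a regulator of meiotic entry, rose from 8.02 ± 7.44 to 64.7 ± 8.83 CPM (2.84 ± 0.54, adjusted p = 0.000207). Of 36 G2 and mitosis genes 6 were lower and none higher (3 and 0 adjusted over the list alone; median -0.32; camera adjusted p = 0.00677), and adjusted p = 0.519 with an estimated correlation (range over its alternatives 0.00193 to 0.519). Cenpf fell from 1703 ± 323 to 463 ± 16.1 CPM (-1.88 ± 0.21, adjusted p = 6e-08). Of 31 S phase genes 3 fell and 1 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.708).

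Among chromatin genes Tet1 was at 8.90 ± 6.69 CPM at P2 (-4.44 ± 0.57, adjusted p = 1.12e-06), Uhrf1 rose from 37.7 ± 6.93 to 186 ± 21.6 (2.32 ± 0.36, adjusted p = 1.8e-05) and Cbx1 fell from 604 ± 182 to 121 ± 35.2 (-2.34 ± 0.35, adjusted p = 2.6e-05). The liver and yolk sac gene Afp had no tag at E13.5 and 105 ± 26.7 CPM at P2, at least 50.3-fold higher, from a cluster 14136 bp from the annotated 5′ end. Of 11 immediate-early and heat-shock genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; median -1.20; camera adjusted p = 0.0259), and adjusted p = 0.586 with an estimated correlation (range over its alternatives 0.000786 to 0.586). The call was lost without E13.5 replicate 3 (0.192) and without P2 replicate 2 (0.0668). Hsph1, a heat-shock protein, fell from 252 ± 13.3 to 82.3 ± 13.7 CPM (-1.61 ± 0.31, adjusted p = 0.000215). Of 15 Sertoli markers 1 rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.356), with sums of 1239 ± 490.1 CPM at E13.5 and 798 ± 700.3 at P2. Median, mean and test differed in sign for DNA methylation (0.13, 0.34 and down), Polycomb genes (-0.36, 0.003 and down) and S phase genes (0.07, -0.033 and down). Without P2 replicate 2 the count fell to 861, and without the 4 Sertoli-high libraries it was 1517 (1114 of them among the 1374) and with the covariate 1401. Scaling by total tags alone moved the median of all genes to 0.32 and gave 1128 genes higher and 325 lower, and scaling by tags in clusters moved it to 0.19 and gave 954 and 482.

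**Figure D3:**
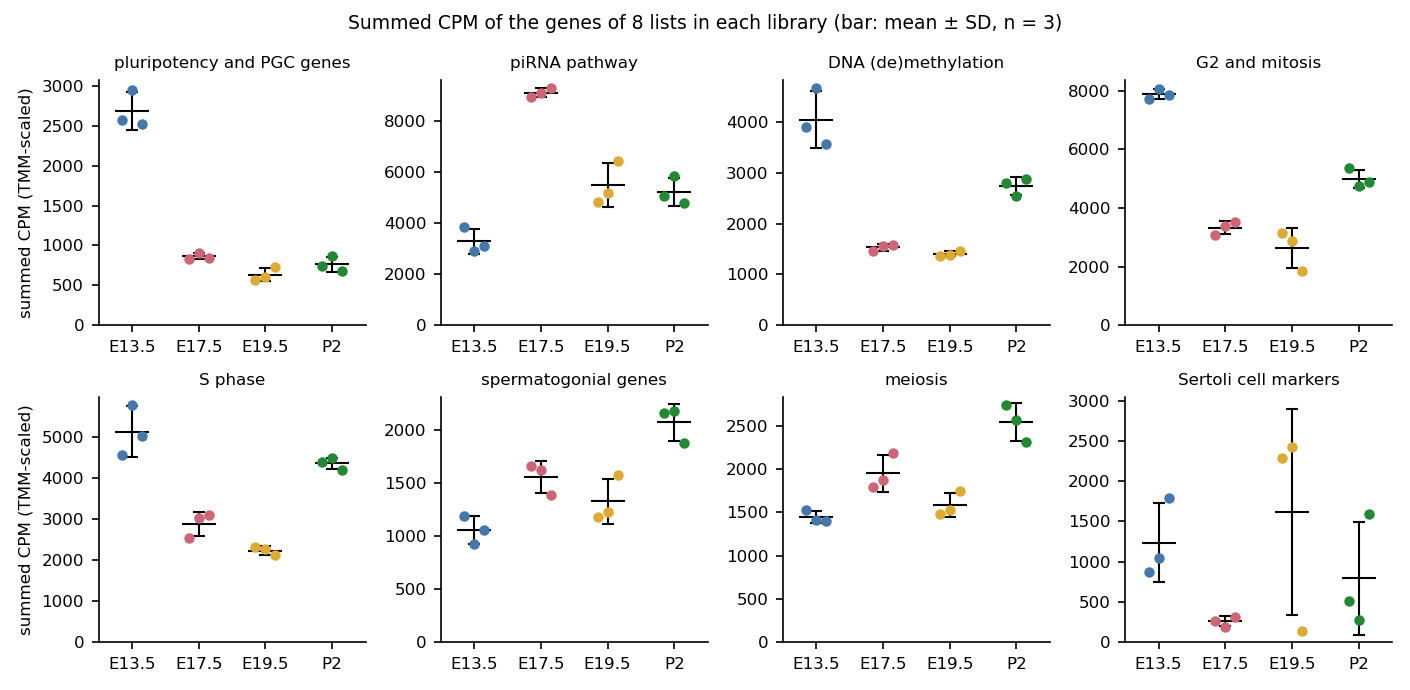
Summed level of 8 gene lists in each library (CPM), one point per library and stage on the x axis, with the mean and SD of 3 libraries. Summed piRNA pathway genes average 9092 ± 177 CPM at E17.5, against 3278 ± 496 at E13.5.

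**Figure D4:**
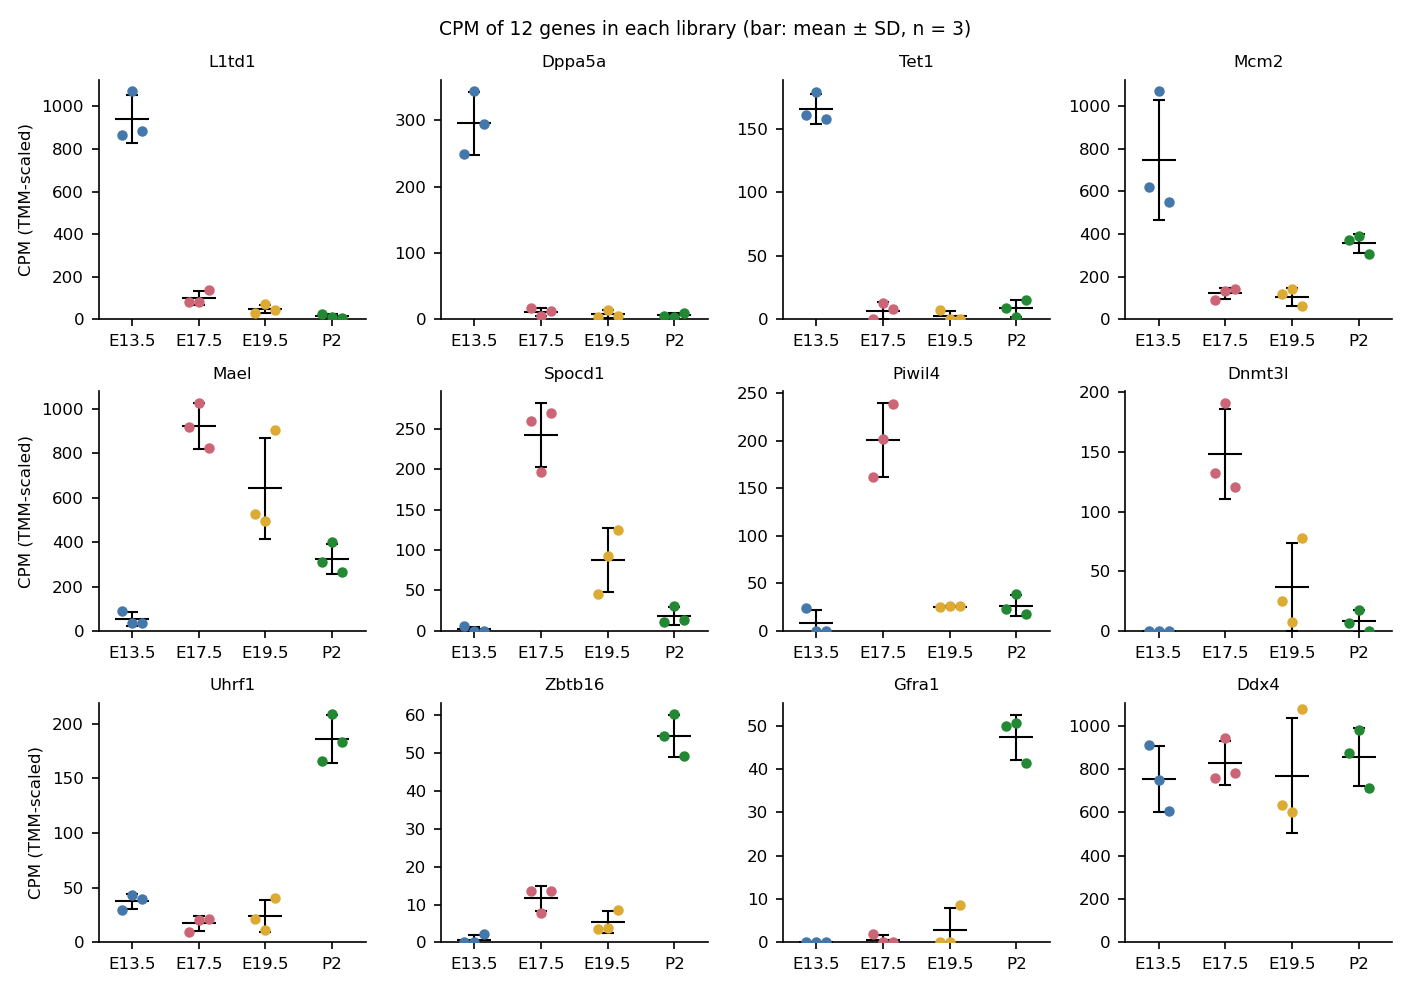
Level of 12 named genes in each library (CPM), stage on the x axis, one point per library with the mean and SD of 3 libraries. L1td1 averages 940.4 ± 112.9 CPM at E13.5 and 15.5 ± 10.3 at P2.

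The list calls above rest on camera, which ranks a list against the other genes. Fry, which tests a list's own genes, called 25 of the 68 list results as well, and 18 were called by both. Fry alone called meiosis (0.000876) and glycolysis (0.00453) higher and DNA methylation (0.00895) and H3K9 methylation genes (0.00274) lower at E17.5 than at E13.5. It alone also called imprinted genes higher at E19.5 than at E17.5 (0.0483), and at P2 against E13.5 glycolysis genes higher (0.0108) and H3K9 methylation genes lower (0.013). Camera alone made 7 calls: Sertoli markers between E13.5 and E17.5 (fry 0.149) and between E17.5 and E19.5 (0.141), ribosomal proteins between E17.5 and E19.5 (0.213) and between E19.5 and P2 (0.304), stress genes between E17.5 and E19.5 (0.139) and between E13.5 and P2 (0.123), and G2 and mitosis genes between E13.5 and P2 (0.0713).

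A group of genes peaked or dipped at E17.5. There were 277 genes higher at E17.5 than at both E13.5 and E19.5, and 268 lower than at both. Mov10l1, Piwil4 and Piwil2 were among the first group, with Piwil2 falling from 355 ± 87.3 to 179.7 ± 53.5 CPM. That Piwil2 fall was lost without E17.5 replicate 1 (0.0509) or 3 (0.0743) and without E19.5 replicate 1 (0.11) or 2 (0.0541), in a range of 0.00312 to 0.466 over its alternatives. Noise in the shared E17.5 libraries alone can give such opposite calls. In 20 sets of data simulated with each gene changed in 1 step alone, chosen after seeing the data, at most 15 genes were higher and 18 lower at E17.5 than at both neighbours, with 361 to 434 genes called between E17.5 and E19.5. The simulated noise was drawn for each gene on its own, so a deviation of a whole library shared by many genes is not covered. The 277 became 150 without E17.5 replicate 3, 133 without E19.5 replicate 1, 111 with the Sertoli covariate (101 of them among the 277) and 56 without the 4 Sertoli-high libraries (49 shared), and the 268 became 85 with the covariate and 43 without the 4 libraries. With total tags alone as scale there were 148 genes in the first group and 366 in the second, and with tags in clusters 210 and 355.

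Tested as the deposited start site clusters instead of genes, chosen after seeing the data, 3168 of 7145 clusters changed between E13.5 and E17.5 (1763 higher, 1405 lower), 757 between E17.5 and E19.5 (336 and 421), 434 between E19.5 and P2 (183 and 251) and 1483 between E13.5 and P2 (831 and 652). Across the 4 stages 3638 clusters changed, and 307 were higher and 252 lower at E17.5 than at both neighbours. The balance of directions depended on the scale. With total tags alone 1434 clusters were higher and 1656 lower in the first step, 382 and 194 in the second, 539 of 652 higher between E19.5 and P2 and 1274 and 326 between E13.5 and P2, and 145 peaked and 300 dipped at E17.5. With tags in clusters the numbers were 1752 and 1474, 408 and 274, 263 and 182, 1105 and 455, and 211 and 304. The 757 became 292 without E17.5 replicate 3, 319 without E19.5 replicate 1 and 446 without E19.5 replicate 2, and the 434 became 212 and 191 without E19.5 replicates 1 and 2 and 170 and 128 without P2 replicates 1 and 2. The 307 became 146 without E17.5 replicate 3, 153 without E19.5 replicate 1 and 203 without E19.5 replicate 2. With the Sertoli covariate the 757, 434 and 307 became 270, 527 and 116, and without the 4 Sertoli-high libraries 200, 133 and 71.

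Among genes used as germ cell landmarks, Ddx4, Dazl and Sycp3 had no call. Ddx4 was at 756 ± 153, 828 ± 102, 769.5 ± 266 and 854 ± 134 CPM over the 4 stages, and its adjusted p-values lay between 0.606 and 0.819. Dazl, an RNA-binding protein of germ cells, was at 202 ± 34.9, 189 ± 25.04, 299 ± 171 and 294 ± 56.4 CPM, with no call in the 4 comparisons. Sycp3, of the synaptonemal complex, was at 14.04 ± 9.22, 19.8 ± 3.48, 43.7 ± 17.53 and 28.6 ± 8.86 CPM, also with no call. The E19.5 means hide a split between replicates. Ddx4 was at 632 and 601 CPM in the Sertoli-high replicates 1 and 2 and at 1076 in replicate 3. Dazl was at 220, 182 and 494.5 there, while Sycp3 went the other way (39.1, 63.1 and 28.9). Whether RNA of other cells lowered the share of germ cell RNA in replicates 1 and 2 was not tested. Kit, the receptor of stem cell factor, fell from 43.0 ± 15.7 to 9.29 ± 3.52 CPM (-2.09 ± 0.67, adjusted p = 0.0108) and was at 20.2 ± 13.4 at P2. No deposited cluster was assigned to Nanos2. Of 8 Nodal signalling genes with a cluster 4 were tested, and summed levels were 225 ± 13.3, 121 ± 9.50, 142 ± 33.2 and 143 ± 22.4 CPM over the stages. The 4 mitochondrially encoded protein genes with a cluster summed to 1114 ± 288, 1128 ± 564, 1898 ± 467 and 1016 ± 357 CPM, and the 3 oocyte genes to 224 ± 62.3, 50.6 ± 24.6, 98.4 ± 62.7 and 92.5 ± 63.1. Kdm5c alone held 215, 155 and 279 CPM of the oocyte sums of 224.7, 160.8 and 285.5 in the 3 E13.5 libraries. The fall of the oocyte sum after E13.5 is thus mostly that of 1 gene, not of the list. None of the 20 genes of the early embryo's zygotic activation list had a cluster.

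Markers of other testis cells were also read. Leydig cell markers (7 genes with a cluster) summed to 75.6 ± 25.8, 82.8 ± 28.9, 165 ± 118 and 112.6 ± 25.7 CPM from E13.5 to P2. At E19.5 Hsd17b3 alone held 117, 167 and 2.89 CPM of the sums of 181.1, 274.5 and 40.5 in replicates 1, 2 and 3. The higher E19.5 sum thus came mostly from 1 gene in the 2 Sertoli-high replicates, so it is no reading of Leydig cells as such. Peritubular and stromal markers (7 genes) summed to 16.2 ± 11.9, 102 ± 41.8, 78.0 ± 26.1 and 68.1 ± 16.6 CPM, and endothelial markers (5 genes) to 11.6 ± 3.0, 49.4 ± 8.70, 58.5 ± 36.4 and 62.2 ± 23.9. Macrophage markers (3 genes) summed to 0.7 ± 1.20, 26.7 ± 18.3, 21.1 ± 13.6 and 67.0 ± 26.9 CPM. Fcer1g, an Fc receptor subunit of myeloid cells, went from 1 tag at E13.5 to 96 at P2, a ratio of 72.1-fold (counting interval 12.6 to 2878). The 1 erythroid gene with a cluster had 9.30 ± 9.20 CPM at E17.5 and no tag at E19.5.

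Replication-dependent histone genes were lowest at E17.5. Summed over 40 genes with a cluster they took 4829 ± 1022 CPM of tags in genes at E13.5, 1125 ± 331 at E17.5, 2265 ± 673 at E19.5 and 3507 ± 265 at P2. The stage effect had p = 0.00014 in a permutation test of the stage labels and 0.00126 after adjustment over 9 families, and no other family passed. Genes on chromosome X summed to 24806 ± 1012, 20698 ± 1198, 24529 ± 530.2 and 24350 ± 845 CPM (permutation adjusted p = 0.0627, 0.0297 without E13.5 replicate 2 and 0.0199 with total tags as denominator, in a range of 0.0199 to 0.105 over the alternatives). Genes on Y gave a permutation adjusted p of 0.133 (0.0199 with total tags as denominator, in a range up to 0.359), mitochondrially encoded genes 0.349, pseudogenes 0.253, long noncoding RNA genes 0.145, protein-coding genes 0.257, ribosomal RNA genes 0.349 and tandem families in gene-poor regions 0.349 (0.0395 without E19.5 replicate 3, the lowest of their alternatives). With 3 libraries against 3 the exact two-sided permutation test cannot go below 0.1, which the histone total reached at each of the 3 consecutive steps, being lower at E17.5, then higher at E19.5 and at P2.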

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

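The cluster tests, tags in clusters as scale, the 5′-end restriction, the total-tag denominator of family totals, the Sertoli covariate and the removal of 4 Sertoli-high libraries were chosen after the results were seen. The settings named below are those that moved a count or turned a direction furthest, and the cause was not tested. Leaving out 1 library at a time gave 2411 to 3156 changed genes between E13.5 and E17.5, 320 to 977 between E17.5 and E19.5, 202 to 652 between E19.5 and P2, 861 to 1615 between E13.5 and P2, 2987 to 3769 across the stages and 133 to 333 peaking at E17.5. The second count was 343 without E17.5 replicate 3, 320 without E19.5 replicate 1 and 433 without E19.5 replicate 2, and the third 279 and 266 without E19.5 replicates 1 and 2 and 202 and 232 without P2 replicates 1 and 2. The fourth was 861 without P2 replicate 2, and the peak count 150 without E17.5 replicate 3 and 133 without E19.5 replicate 1. For clusters the ranges were 2806 to 3917, 292 to 970, 128 to 594, 989 to 2054, 3370 to 4578 and 146 to 382, for called lists 22 to 28 of 68 and for families 1 to 2.

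With the Sertoli covariate 290 genes changed between E17.5 and E19.5 and 111 peaked at E17.5, as did 116 clusters, and 2073 and 270 clusters changed in the first and second steps. The median of the Sertoli list between E13.5 and E17.5 turned to 0.41, which says little as the covariate is the sum of that list. Without the 4 Sertoli-high libraries, which leaves 1 library at E19.5, 171 genes changed in the second and 171 in the third step and 56 peaked, and 4795, 200, 133 and 2427 clusters changed in the 4 comparisons and 71 peaked. In that setting Ldhb (-0.077), Mro (-2.46) and Hsd17b3 (-0.999) turned negative between E17.5 and E19.5, as did the Sertoli list (-0.89), the ribosomal list's test turned up at a median of -0.016, and the Sertoli list turned to 1.61 between E19.5 and P2. The turns of the Sertoli list and of its member Mro follow from choosing the libraries by that list's sum and are no separate result. Hsd17b3 (117 and 167 CPM) and Ldhb (71.0 and 44.5) were also higher in the E19.5 libraries left out than in replicate 3 (2.89 and 11.6). Their turns are therefore no separate result either. Total tags alone as scale gave 760 genes and 652 clusters between E19.5 and P2 and 148 genes and 145 clusters peaking. No filter gave 7123 clusters in the first step, 7805 across the stages and 180 peaking. A CPM of at least 5 in 3 libraries gave 7582, 8076 and, between E13.5 and P2, 2639. Both tested more clusters than filterByExpr, although the second was planned as a stricter filter. Only the 6 libraries compared gave 458 clusters in the second step and 197 peaking. With an estimated correlation 6 lists were called, and with total tags as denominator 3 families. From clusters near the 5′ end alone Lig1 turned to higher at P2 than at E13.5 (2.51).

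A replicate block gave 2656, 582, 395 and 1275 changed genes in the 4 comparisons, 3071 across the stages, 228 peaking and 25 called lists. No pairing by replicate number was seen. Over 18 pairs of same-numbered libraries of different stages, correlations of deviations from the stage mean lay between -0.313 and 0.106. Pairs with different numbers were not compared, so these values cannot exclude something shared by replicate number. Of 241 called changes of named genes 146 kept direction and call under all settings run for them. So did 6 of 25 called lists, for which fewer settings were run. Simulated 2-fold changes were called in 14% to 21% of genes.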

Other observations

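A list of axonemal genes, which encode parts of motile cilia and sperm tails, was chosen after the named genes were seen, and so were the pairs of start sites that follow. Of its 15 tested genes 11 rose between E13.5 and E17.5 and none fell (median log2 ratio 4.29; camera p = 1.31e-11, 0.00128 with an estimated correlation). Between E17.5 and E19.5 none rose and 6 fell (p = 1.71e-06, 0.00634 with an estimated correlation), and between E19.5 and P2 none rose and 7 fell (7.38e-06, 0.00555 with an estimated correlation). At P2 9 of the 15 were still higher than at E13.5 and 1 was lower (0.00104, 0.0364 with an estimated correlation). Cfap300 was at 8.72 ± 3.22 CPM at E13.5, 174 ± 22.8 at E17.5, 103 ± 28.8 at E19.5 and 45.3 ± 18.3 at P2. The list was chosen from genes that showed the pattern, so its test is not independent evidence.

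Some genes had start sites called in opposite directions. Over all 7145 clusters tested 1763 rose and 1405 fell between E13.5 and E17.5, so unrelated clusters of a gene would also give opposite pairs. The number expected that way was not computed, and the share of each start site within its gene was not tested. The counts below are therefore no evidence of more opposite pairs than unrelated clusters would give. Of 493 genes with at least 2 tested clusters, 62 had 1 cluster that rose and another that fell between E13.5 and E17.5, in 38 of them more than 500 bp apart, and 22 did between E13.5 and P2 (17 of them over 500 bp apart). Between E17.5 and E19.5 there was 1 such gene, and none between E19.5 and P2. In Lef1, a transcription factor of Wnt signalling, a cluster at chromosome 3, 131112465 to 131112579, rose (2.19 ± 0.65, adjusted p = 0.00699) and one 2197 bp upstream, 131110268 to 131110350, fell (-5.71 ± 0.90, adjusted p = 1.27e-05), while the gene's sum was at 86.0 ± 12.9 and 86.7 ± 28.4 CPM. In Lig1, the replicative DNA ligase, the cluster at chromosome 7, 13277153 to 13277300, rose (3.59 ± 0.57, adjusted p = 2.6e-05) and that at 13285259 to 13285363 fell (-2.17 ± 0.61, adjusted p = 0.00533). In Msi1, an RNA-binding protein of progenitor cells, a cluster at chromosome 5, 115430562 to 115430690, rose (6.11 ± 0.80, adjusted p = 8.62e-07) and one 960 bp away fell (-1.69 ± 0.62, adjusted p = 0.0282). In Actb the cluster at 142905679 to 142905858 rose (2.73 ± 0.31) and that at 142906697 to 142906766 fell (-1.27 ± 0.27).

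Of the tests that follow, those of liver and heart muscle RNA, of the deposited cluster set, of a wrong label and of Sertoli RNA in E19.5 replicates 1 and 2 were chosen after the result was seen. Many genes with no tag at E13.5 were read at E17.5: 690 had 0 tags at E13.5 and at least 10 at E17.5, against 56 the other way. A difference in depth is argued against, since after thinning every library to 174575 tags in genes the lowest E17.5 library still had 525 more genes with a tag than the highest E13.5 library (means 9778 ± 355 and 8759 ± 228), and pools thinned to 563972 tags gave 398 against 79 genes. RNA of liver or heart muscle cells may add to it and cannot be told apart here. The markers with a cluster (4 of 14 and 3 of 12) had a median of 15.14 CPM at E17.5. The highest were Fgg at 27.56 and Ttn at 43.78, against 119 for Afp and 107 for Myh6. Tnni3 went the other way, from 4.53 CPM at E13.5 to 0 at E17.5. No cluster was assigned to the others, such as Alb and Tnnt2, and with these set to 0 each list had a median of 0. Their absence goes against such RNA unless the rule that built the clusters, or the reading of strands, left them out. A deposited cluster set that left out start sites used at E13.5 also stays open, although the share of tags in clusters was 7.2 points higher at E13.5 (73.0 ± 7.5% against 65.8 ± 1.3%), because the rule that built the clusters is not given in the sources used here. The excess was not particular to E17.5. The same thinned pools gave 349 against 21 genes for E19.5 against E13.5, and 178 against 35 for P2 against E13.5. A real gain of transcripts with age is the biological candidate and was not tested on its own.

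E19.5 replicate 3 stood apart from E19.5 replicates 1 and 2 and correlated more with the E17.5 libraries (0.804 to 0.840) than with them (0.787 and 0.742). An E17.5 library under a wrong label is argued against: over genes that separate E17.5 (0) from P2 (1), its median position was 0.458, against 0.075 to 0.183 for the E17.5 libraries and 0.564 and 0.528 for E19.5 replicates 1 and 2, and the E17.5 libraries correlated more with each other (0.879 to 0.901) than with it. A difference in depth is argued against by the depths themselves, which were 174575, 177570 and 211827 tags in genes for replicates 1, 2 and 3. Thinning such similar libraries could change little, so its result adds little. After thinning, replicates 1 and 2 correlated more across genes with each other (0.852) than with replicate 3 (0.799 and 0.758). The gap to the higher of these was 0.053. Sertoli cell RNA in replicates 1 and 2 may be part of it and cannot be told apart: over 6129 genes outside the marker list the difference between them and replicate 3 correlated by 0.291 with that between P2 replicate 3 and the other P2 libraries, and by 0.078 with that between E13.5 replicate 3 and the other E13.5 libraries. A difference in age or in the cells between litters stays open and untested.

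Fewer of the 749 changes between E17.5 and E19.5 were called with the Sertoli markers as a covariate, which was added after the markers were seen to differ between libraries, in a test written before its result was seen. With the marker sum as a covariate 31.1% of the 370 rises were still called, their median log2 ratio going from 1.64 to 1.28 and its median SE from 0.43 to 0.47, and 99.5% kept their sign. Of the 379 falls 40.1% were still called, the median going from -1.23 to -1.15 (SE 0.31 to 0.35). Over the 255 lost rises the median went from 1.65 to 1.11 (SE 0.47 to 0.51) and over the 227 lost falls from -1.10 to -0.94 (SE 0.33 to 0.37), with both a smaller ratio and a wider error in 83.1% and 78.4% of them, a reading chosen after the result was seen. Sertoli cell RNA may be the cause of part of these changes. Only E19.5 replicate 3 (138 CPM of markers) was as low as the E17.5 libraries (162 to 275). Telling this RNA from stage therefore rests on 1 library. Some rises were read mainly in E19.5 replicates 1 and 2, such as Hsd17b3 (117, 167 and 2.89 CPM in replicates 1, 2 and 3). Others were read in all 3, such as Dmrt1 (131, 145 and 179).

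Other splits of the libraries were fitted in the same way, and in each case 1 split, the real one, gave as large a count. For the 4 comparisons 10 splits exist, too few for a share under 0.05: the real counts were 2809, 749, 495 and 1374 genes and the highest others 0, 3, 90 and 0, and for clusters 3168, 757, 434 and 1483 against 0, 2, 70 and 0. For the test across 4 stages and for genes peaking at E17.5 100 splits were drawn. The real values were 3274 and 277 genes against at most 866 and 0 in other splits. For clusters they were 3638 and 307 against at most 876 and 0. Other splits mix libraries of different stages, which widens the spread within groups, so few calls were likely in them. They cannot decide whether noise in the shared E17.5 libraries makes genes peak.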
